A study of Homo sapiens with 6 samples.

How the data were processed

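Gene expression was measured in MDA-MB-231 cells, an established human breast cancer cell line of mesenchymal appearance that lacks the oestrogen receptor. Per the labels, cells received either an expression plasmid for HS3ST2, which encodes a heparan sulfate 3-O-sulfotransferase, or a control vector, with 3 independent replicates of each. Total RNA was purified with a column kit and biotinylated cRNA was made from 3.6 µg of it for Affymetrix arrays, per the labels' protocols. How long after transfection RNA was taken, whether cells were selected or cloned, and whether replicates were separate transfections are not given in the sources used here. The p-values therefore measure the spread between these arrays.

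The deposited table holds 54675 probe sets and 1 column for each of the 6 arrays. The submitters' processing notes name RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of a probe set as a log2 value. The deposited log2 values are not RMA levels. The median of the 6 values was 0 for every probe set within 1e-05, so each probe set had been centred on its own median over the arrays, by software not given in the sources used here. Differences between arrays survive this step, but the level of a probe set does not, so it cannot be said which probe sets lie near background. The base of the logarithm is not stated and was taken as 2, the base that RMA writes. Arrays give no counts, and the number of arrays limits the precision.

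From these values, 62 Affymetrix control probe sets were set aside and 54613 probe sets were tested. GEO's platform annotation gave 1 gene symbol for 41091 of them, several for 1801 and none for 11721. Of those with 1 symbol, 41037 were matched to a current gene record by gene number. Only probe sets with 1 symbol were used for genes. The design called for the probe set with the highest mean level to represent a gene. Centring removed the levels, so the probe sets of a gene were averaged instead, which gave 19775 genes, of which 10523 had more than 1 probe set. In 78 genes single probe sets passed the threshold in both directions.

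The HS3ST2-labelled arrays were compared with the control vector arrays by limma 3.58.1 (lmFit and eBayes, R 4.3.3) with no covariate, once over probe sets and once over genes. A change was called at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 differences, HS3ST2-labelled minus control, with the moderated standard error and n = 3 per group unless stated. On simulated arrays with the spread of the real genes, 50% of genes changed by 0.3 log2, 92% of those changed by 0.5 and 100% of those changed by 1 were called among 19775 genes, with 10 false calls. For probe sets the shares were 0%, 54% and 100%, with 4 false calls among 54613. Only 50 features were planted at each size, far fewer than the 4845 genes and 9220 probe sets called in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares understate what the real comparison could call. There the probe sets of FDPS (-0.26) and ACAT2 (-0.29) were called.

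The groups, the tests, the named-gene rule, the alternatives and 22 gene lists were fixed before the data were examined. The lists named 565 genes, of which 523 were measured, with older symbols matched through a current gene table. The protease, cadherin, Wnt and ERK lists were chosen knowing that published work on this enzyme in these cells concerns those themes. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 22 lists. In data simulated with independent genes, a list lowered by 0.3 log2 was called and none of the other lists was. This does not check the test where genes of a list vary together. The estimated correlation was 0.182 for the cell cycle list. The genes named are HS3ST2, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 members of each list with the smallest p among those called, and 12 genes fixed by name.

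The alternatives were a replicate block, leaving out each array, quantile normalization or median centring of the deposited values, array weights, other thresholds, probe sets ending in _x_at or _s_at left out, camera with an estimated correlation, and fry. Robust eBayes without an intensity trend and the use of the probe set with the largest SD were chosen after seeing the data. Both planned filters on dim probe sets, cyclic loess and both intensity-trend settings need levels and were not run. No genome build is named in the file, so no coordinates are given.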

Results

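The data were 6 arrays of MDA-MB-231 cells, 3 from cells given a control vector and 3 from cells given an HS3ST2 expression plasmid. The design has 1 comparison, which asks which genes differ in expression between these cells. The median absolute difference between arrays over 54613 probe sets was 0.1 to 0.122 log2 within a group and 0.16 to 0.193 between groups. All values are relative to each probe set's median over the 6 arrays, so levels of different genes cannot be compared.

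The single probe set for HS3ST2 was not detectably higher in the arrays labelled HS3ST2. Its values were -0.22, 0.17 and -0.11 in the control arrays and 0.16, 0.04 and -0.04 in the HS3ST2-labelled arrays. The difference was 0.11 ± 0.10 log2 (SE, n = 3 per group), with a 95% interval from -0.13 to 0.35 and a limma adjusted p of 0.523. Whether this probe set matches the transcript made from the plasmid is not given in the sources used here, so it does not check the labels. The arrays are therefore called HS3ST2-labelled throughout, and every direction below rests on the labels.

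The largest rise in the HS3ST2-labelled arrays was that of SFTA3, a surfactant-associated gene, which rose by 6.74 ± 0.10 log2 (SE), a 107-fold difference on this scale. NKX2-1, a transcription factor of lung and thyroid and the neighbour of SFTA3 in the genome, rose by 3.73 ± 0.13 over its 2 probe sets, which gave 5.68 and 1.78. The trefoil factors TFF2, TFF1 and TFF3, small secreted proteins of mucosal surfaces, rose by 3.92 ± 0.11, 3.04 ± 0.09 and 2.54 ± 0.05. The other large rises were in MAGEA6, a cancer-testis antigen (2.85 ± 0.11), ALPP, placental alkaline phosphatase (2.76 ± 0.13), THBS2, a matrix glycoprotein (2.73 ± 0.19), LRRC2 (2.69 ± 0.16), FGG, the fibrinogen gamma chain (2.66 ± 0.11), the membrane protease gene TMPRSS3 (2.64 ± 0.08) and WFDC10B (2.54 ± 0.11). MAGEA6 belongs to a family of near-identical genes whose probes can share signal.

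Among the 12 largest falls, CTHRC1, a secreted collagen-repeat protein, fell by 3.19 ± 0.10 log2 (SE), and the chemokine CCL20 fell by 2.15 ± 0.13. IL24, a cytokine, fell by 1.89 ± 0.09, and the chemokine CXCL5 fell by 1.61 ± 0.06. CALB2, which encodes calretinin, fell by 2.11 ± 0.25, and the nuclear body gene SP140 fell by 1.96 ± 0.06. HSPA6, an inducible heat shock protein, fell by 1.77 ± 0.08. APCDD1L fell by 1.75 ± 0.09, CRTAM by 1.71 ± 0.09, HKDC1, a hexokinase-like gene, by 1.68 ± 0.06, MLLT11 by 1.65 ± 0.08 and DEPDC7 by 1.57 ± 0.11. All 24 of these genes had an adjusted p of 6.39e-04 or less by limma. Without probe sets ending in _x_at or _s_at, CXCL5 was at -0.31 and was not called (limma adjusted p 0.105).

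**Figure D1:**
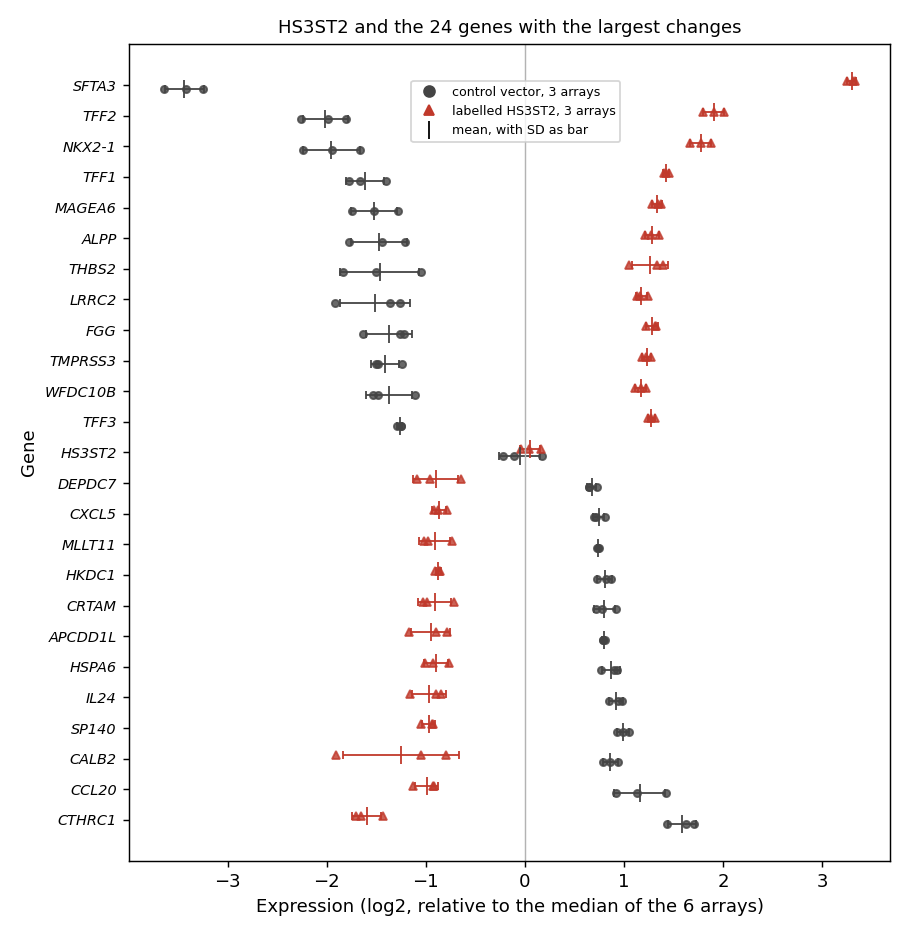
Expression of HS3ST2 and of the 12 genes with the largest rises and the 12 with the largest falls, in log2 relative to the median of the 6 arrays (x axis), with 1 point per array and bars for mean and SD. The 24 changed genes were picked among genes whose groups do not overlap. HS3ST2 was not picked that way, and its values overlap between the groups.

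In all, 4845 of 19775 genes (24.5%) differed at an adjusted p under 0.05 by limma, 2274 higher and 2571 lower in the HS3ST2-labelled arrays. The median size of a called change was 0.345 log2, and 98 genes were higher and 93 lower by at least 1 log2. Among probe sets, 9220 of 54613 differed, 4315 higher and 4905 lower. The groups did not overlap for 40.4% of genes, where chance gives 10% for 3 against 3.

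Cell cycle genes were lower in the HS3ST2-labelled arrays almost throughout the list. Of 36 measured genes, 32 fell, none rose and 4 did not pass, and the count was also 32 when adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, fell by 1.49 ± 0.07 log2 (SE), and the mitotic kinesin KIF20A fell by 1.35 ± 0.07. CENPE, another mitotic kinesin, fell by 1.12 ± 0.06, and the spindle assembly factor TPX2 fell by 1.08 ± 0.06. The list's mean was 0.36 ± 0.05 (SD, n = 3) in control arrays and -0.34 ± 0.01 in HS3ST2-labelled arrays. The list was called by camera (adjusted p = 5.3e-23), but not with an estimated correlation (adjusted p = 0.132 with an estimated correlation). The median of the ribosomal RNA control probe sets was higher in the HS3ST2-labelled arrays too. It was -0.18 ± 0.12 (SD, n = 3) in control arrays and 0.31 ± 0.38 in HS3ST2-labelled arrays (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Without HS3ST2 replicate 3, where that signal was highest, 32 cell cycle genes were lower.

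Genes of NF-kB signalling and inflammatory cytokines were also lower. Of 31 measured genes, 14 fell, 1 rose and 16 did not pass, and adjusted over the list alone 16 fell and 1 rose. Besides CCL20, IL24 and CXCL5, VCAM1, an adhesion molecule for leukocytes, fell by 1.48 ± 0.05 log2 (SE) and the cytokine IL6 fell by 1.10 ± 0.06. The gene that rose was TNFAIP3, an inhibitor of NF-kB signalling (0.76 ± 0.05), named here after its value was seen. The list was called by camera (adjusted p = 1.97e-06) and not with an estimated correlation (adjusted p = 0.132 with an estimated correlation). Without HS3ST2 replicate 3, where the ribosomal RNA probe sets were at 0.74, 13 genes were lower and 1 was higher. Of the 24 genes measured without the _x_at and _s_at probe sets, 9 fell.

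Genes of the unfolded protein response were more often higher than lower. Of 26 measured genes, 9 rose, 3 fell and 14 did not pass, and adjusted over the list alone 13 rose and 4 fell. CHAC1, a glutathione-degrading enzyme induced by stress, rose by 1.21 ± 0.07 log2 (SE), the transcription factor ATF4 by 0.63 ± 0.05, CRELD2 by 0.61 ± 0.06 and HERPUD1 by 0.46 ± 0.06. Camera called the list (adjusted p = 0.0153), but not with an estimated correlation (adjusted p = 0.46 with an estimated correlation) and not without the _x_at and _s_at probe sets (adjusted p = 0.107), where HERPUD1 was not called either (0.08). Without HS3ST2 replicate 3, the array with the highest ribosomal RNA signal, 8 genes were higher and 2 lower.

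Genes of hypoxia and glycolysis were more often lower. Of 29 measured genes, 10 fell, 2 rose and 17 did not pass, against 11 and 3 adjusted over the list alone. ADM, a vasodilator peptide, fell by 0.95 ± 0.05 log2 (SE), the aldolase gene ALDOC by 0.56 ± 0.05 and NDRG1 by 0.40 ± 0.05, while VEGFA rose by 0.46 ± 0.06. The camera call was marginal (adjusted p = 0.0447, and adjusted p = 0.295 with an estimated correlation). The adjusted p was 0.034 to 0.0708 over left-out arrays, and the call was lost without control replicate 2 (0.0577), HS3ST2 replicate 1 (0.0634) or HS3ST2 replicate 3 (0.0708), the array with the highest ribosomal RNA signal, where 8 genes were lower and 2 higher. It was also lost with quantile normalization (0.0538), without the _x_at and _s_at probe sets (0.107) and with the probe set of largest SD (0.154). In the last of these 10 genes fell and 4 rose, and without the _x_at and _s_at probe sets 5 of 17 fell and 2 rose.

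**Figure D2:**
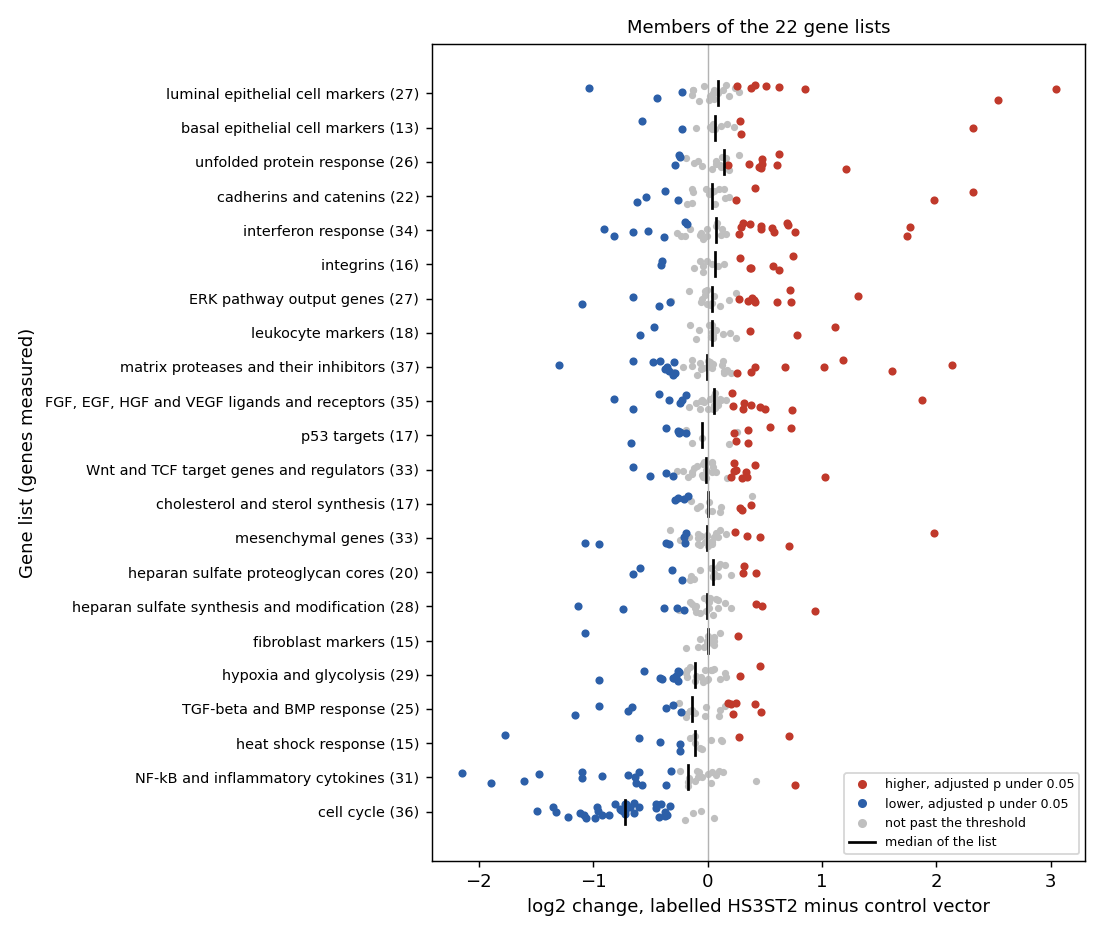
The log2 change, HS3ST2-labelled minus control vector (x axis), of each measured member of the 22 gene lists (y axis, number measured in parentheses), with the list's median as a black line. Cell cycle genes lie to the left, with a median of -0.72, while most other lists hold members on both sides of 0.

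Among enzymes of heparan sulfate synthesis and modification, 3 of 28 measured genes rose, 5 fell and 20 did not pass, with equal counts adjusted over the list alone. HPSE, the heparanase that cleaves heparan sulfate, fell by 1.13 ± 0.06 log2 (SE). HS3ST3B1, another 3-O-sulfotransferase, fell by 0.74 ± 0.06, and EXT2, a subunit of the chain polymerase, fell by 0.38 ± 0.05. The 6-O-sulfotransferase HS6ST3 rose by 0.94 ± 0.07. The list as a whole was not called (adjusted p = 0.576 by camera), and without the _x_at and _s_at probe sets 3 of 24 rose and 3 fell. Of 20 measured proteoglycan cores and related carriers, 3 rose and 4 fell, also adjusted over the list alone, against 3 and 2 of 16 without the _x_at and _s_at probe sets. CD44, the hyaluronan receptor, fell by 0.59 ± 0.05, while SDC3 rose by 0.42 ± 0.08, GPC6 by 0.32 ± 0.06 and NRP1 by 0.31 ± 0.05. The probe sets of these risen genes disagreed, with SDC3 at 0.11 and 0.73, GPC6 at 0.12 and 0.52, and NRP1 from -0.05 to 0.84. SDC1 (-0.14 ± 0.05, adjusted p 0.097), SDC2 (0.03 ± 0.05, adjusted p 0.725) and SDC4 (0.04 ± 0.06, adjusted p 0.668) did not pass.

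Matrix proteases and their inhibitors moved in both directions. Of 37 measured genes, 8 rose, 10 fell and 19 did not pass, and adjusted over the list alone 10 rose and 10 fell. The collagenases MMP13 and MMP1 rose by 2.14 ± 0.11 and 1.61 ± 0.07 log2 (SE), PLAT, tissue plasminogen activator, by 1.19 ± 0.05, and TIMP3, a metalloprotease inhibitor, by 1.02 ± 0.06. ADAMTS1, a secreted metalloprotease, fell by 1.30 ± 0.06, PLAU, urokinase, by 0.47 ± 0.06 and TFPI2, a serine protease inhibitor, by 0.35 ± 0.06. MMP2 (0.00 ± 0.08, 95% interval -0.19 to 0.19), MMP7 (0.21 ± 0.08, interval 0.03 to 0.38, adjusted p 0.0865) and MMP9 (0.02 ± 0.15, interval -0.32 to 0.37) did not pass, although MMP7 passed without HS3ST2 replicate 2 (0.28, limma adjusted p 0.0242). The list was not called (adjusted p = 0.914 by camera), and without the _x_at and _s_at probe sets 5 of 26 rose and 6 fell.

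Of 22 measured cadherins, catenins and desmosomal genes, 4 rose and 4 fell, with 4 and 5 adjusted over the list alone, against 2 and 3 of 18 without the _x_at and _s_at probe sets. CDH3, P-cadherin, rose by 2.32 ± 0.09 log2 (SE) and CDH11, a mesenchymal cadherin, by 1.98 ± 0.06, with all 4 CDH11 probe sets called. CDH1, E-cadherin, rose by 0.42 ± 0.09, but only 1 of its 2 probe sets was called (0.61, against 0.22 in the other). Both end in _s_at. CDH2, N-cadherin, did not pass (0.04 ± 0.07, interval -0.12 to 0.20). The desmosomal cadherin DSG2 fell by 0.62 ± 0.07 and CTNNAL1 by 0.54 ± 0.06. Of 16 integrins, 6 rose and 2 fell, also adjusted over the list alone. ITGA1 rose by 0.74 ± 0.06, ITGB4 by 0.62 ± 0.09 and ITGAV by 0.37 ± 0.05, while ITGA6 fell by 0.40 ± 0.05. The probe sets of ITGB4 disagreed, since 3 of 5 were called higher and its only probe set without an _s_at ending gave -0.038. Neither list was called (adjusted p = 0.9 and 0.263 by camera).

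Among Wnt regulators and TCF target genes, 9 of 33 rose and 4 fell, with 9 and 6 adjusted over the list alone. Without control replicate 2 or HS3ST2 replicate 3, 4 rose and 4 fell, and 5 rose without control replicate 3 or HS3ST2 replicate 2. Of 26 measured without the _x_at and _s_at probe sets, 7 rose and 1 fell. LRP6, a Wnt co-receptor, rose by 1.03 ± 0.08 log2 (SE), the Wnt inhibitor DKK1 by 0.35 ± 0.05 and the kinase GSK3B by 0.33 ± 0.05, while MYC fell by 0.66 ± 0.05. TCF7L2, a TCF transcription factor of the Wnt pathway, did not pass (0.05 ± 0.05 over 7 probe sets, interval -0.07 to 0.17). Its probe sets ranged from -0.22 to 0.20, and none was called. Of 27 ERK output genes, 9 rose and 4 fell, with 10 and 6 adjusted over the list alone, against 8 and 2 of 23 without the _x_at and _s_at probe sets. The ERK phosphatase DUSP6 rose by 1.31 ± 0.06 and SPRY2, a feedback inhibitor, by 0.72 ± 0.06, while the cytokine IL11 fell by 1.10 ± 0.08. Neither list was called (adjusted p = 0.914 and 0.263 by camera).

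Of 35 growth factor ligands and receptors, 9 rose and 7 fell, with 10 and 7 adjusted over the list alone. FGFBP1, which releases FGFs from the matrix, rose by 1.87 ± 0.14 log2 (SE), VEGFC by 0.73 ± 0.06 and the co-receptor NRP2 by 0.50 ± 0.05, while NRG1 fell by 0.65 ± 0.06, a call lost without the _x_at and _s_at probe sets (-0.29). The 11 probe sets of NRP2 ranged from 0.07 to 1.71, and 5 were called higher. Of 25 TGF-beta and BMP response genes, 6 rose and 7 fell, with 7 and 10 adjusted over the list alone, and 3 rose without control replicate 3 or without any 1 of the HS3ST2-labelled arrays. ID2, an inhibitor of differentiation, fell by 1.16 ± 0.07 and TGFBI by 0.95 ± 0.05, while BHLHE40 rose by 0.41 ± 0.06 and LTBP3 by 0.46 ± 0.06, although LTBP3 gave -0.096 with no call without the _x_at and _s_at probe sets. Of 33 mesenchymal genes, 5 rose and 7 fell, also adjusted over the list alone, and 4 fell without control replicate 1. Collagen VI chains went apart, with COL6A2 higher by 0.71 ± 0.06 and COL6A3 lower (-1.07 ± 0.10). These lists were not called by camera (adjusted p = 0.462, 0.263 and 0.861). Without the _x_at and _s_at probe sets, 6 of 27 growth factor genes rose and 3 fell, 2 of 19 TGF-beta genes rose and 4 fell, and 2 of 26 mesenchymal genes rose and 5 fell.

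Of 34 interferon response genes, 13 rose and 7 fell, with 14 and 7 adjusted over the list alone, and 4 fell without control replicate 3, HS3ST2 replicate 2 or HS3ST2 replicate 3. DDX60 and OASL, both induced by interferon, rose by 1.77 ± 0.05 and 1.74 ± 0.09 log2 (SE), and OAS1 by 0.69 ± 0.05, while RIGI, a cytosolic RNA sensor, fell by 0.91 ± 0.07. Of 15 heat shock genes, 2 rose and 5 fell, with 2 and 6 adjusted over the list alone, and 3 fell without control replicate 2, control replicate 3 or HS3ST2 replicate 2. Besides HSPA6, HSPA4L fell by 0.60 ± 0.05 and the chaperonin gene HSPE1 by 0.42 ± 0.05, while HSPH1 rose by 0.71 ± 0.06. Of 17 p53 targets, 6 rose and 6 fell, with 8 and 6 adjusted over the list alone. Here 3 fell without control replicate 2, HS3ST2 replicate 2 or HS3ST2 replicate 3, and without the _x_at and _s_at probe sets 4 of 11 rose and 1 fell. PHLDA3 rose by 0.73 ± 0.07, XPC, a DNA repair gene, by 0.55 ± 0.06 and PMAIP1 by 0.35 ± 0.05, while GDF15 fell by 0.67 ± 0.08, a call lost without the _x_at and _s_at probe sets (-0.12). Of 17 sterol synthesis genes, 3 rose and 4 fell, with 4 and 6 adjusted over the list alone, and 2 fell when any 1 array other than control replicate 2 was left out. MSMO1 and SREBF1 rose by 0.30 ± 0.05 and 0.28 ± 0.05, while ACAT2 and FDPS fell by 0.29 ± 0.05 and 0.26 ± 0.05. None of these 4 lists was called by camera (adjusted p = 0.183, 0.183, 0.914 and 0.914). Without the _x_at and _s_at probe sets, 12 of 28 interferon genes rose and 3 fell, 2 of 11 heat shock genes rose and 3 fell, and 3 of 13 sterol genes rose and 2 fell. With the probe set of largest SD, 4 heat shock genes rose and 6 fell.

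Of 27 luminal epithelial markers, 8 rose and 3 fell, with 10 and 3 adjusted over the list alone. The list was not called by camera (adjusted p = 0.0672, and 0.0224 to 0.137 over left-out arrays), but was called higher without control replicate 1 (0.0224) and with array weights (0.0416). Besides TFF1 and TFF3, AGR2 rose by 0.85 ± 0.06 log2 (SE), while the carbonic anhydrase CA12 fell by 1.04 ± 0.05, and the list's median was 0.09. Of 13 basal epithelial markers, 3 rose and 2 fell, with 4 and 2 adjusted over the list alone. Besides CDH3, S100A2 rose by 0.29 ± 0.06 and SFN by 0.28 ± 0.05, while KRT15 fell by 0.58 ± 0.10. Of 18 leukocyte markers, 3 rose and 2 fell, also adjusted over the list alone, and 1 fell without control replicate 3, HS3ST2 replicate 1 or HS3ST2 replicate 3. ITGB2, LCP1 and CORO1A rose by 1.11 ± 0.05, 0.78 ± 0.05 and 0.37 ± 0.07, while LAPTM5 fell by 0.59 ± 0.07. Of 15 fibroblast markers, FBLN1 rose by 0.26 ± 0.05 and COL6A3 fell, also adjusted over the list alone. The call of FBLN1 was lost without the _x_at and _s_at probe sets (0.11), and with the probe set of largest SD 1 fibroblast marker rose and 2 fell. Of 13 basal and 17 leukocyte markers measured without the _x_at and _s_at probe sets, 3 rose and 1 fell in each list. The basal, leukocyte and fibroblast lists were not called by camera (adjusted p = 0.323, 0.323 and 0.914). By fry, which does not compare a list with other genes, the luminal, basal and leukocyte lists were called higher (adjusted p = 0.00109, 0.00316 and 0.00208). Median, mean and camera direction differed in sign for the proteoglycan core, protease, Wnt, p53, sterol and fibroblast lists.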

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

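The tests of the plasmid transcript, of admixed epithelial cells, of the 25 lung markers and of copies around NKX2-1 were chosen after some or all of their values had been seen.

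Ribosomal RNA control probe sets, which no comparison used, stood above the control arrays in HS3ST2 replicate 3. Their median over 6 probe sets was 0.740 log2 there, against -0.20, -0.06 and -0.29 in the control arrays. It was 0.02 and 0.16 in HS3ST2 replicates 1 and 2, also above every control array. The median of the poly-A spike-in probe sets was 0.70 in HS3ST2 replicate 3 and -0.86 in control replicate 3.

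HS3ST2 did not stand out in the arrays labelled for it, with a change of 0.11 log2. An exchange of single arrays between the groups is argued against, because limma called 9220 probe sets with the labelled division and 0 with each other division, where 1014 to 2022 had an unadjusted p under 0.05. An exchange of the whole groups would leave those counts as they are and stays open. Whether the probe set misses the plasmid's transcript cannot be told apart from a transgene that was not expressed, since the insert and the probes' place were not analysed here.

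NKX2-1, SFTA3 and the trefoil factors rose by 2.54 to 6.74 log2. Extra copies that raise the wider region as a set are argued against by 20 measured neighbours, with a median change of 0.020 (bootstrap 95% interval -0.10 to 0.10). MBIP (0.64) and NKX2-1-AS1 (0.71) were higher, so a change of a shorter stretch is open. Centring removed the levels of the neighbours, so those too weakly expressed to follow extra copies could not be set aside, which limits this argument. An admixture that raises lung markers as a set is argued against by 20 of them, with a median of 0.0857 (interval -0.0085 to 0.15). All 25, with the genes seen to rise put back, had a median of 0.12 (interval 0.038 to 0.25). SFTPB (1.44), HOPX (1.31) and SFTA1P (1.63) were among those put back. Of the 20, NAPSA (0.45) and FOXA2 (0.26) were called higher and LAMP3 (-0.29) lower, with SFTPC at 0.038 and SCGB1A1 at 0.14 not called. The list pools alveolar and airway cells, and centring removed the levels of its genes. Its median therefore cannot decide on an admixture of 1 such cell type, which stays open. For admixed epithelial cells, 23 genes of such cells had a median of 0.0506 (interval -0.086 to 0.24). Of these, 7 were higher, led by ESRP1 (0.63) and GRHL1 (0.43), and 3 lower, ST14 (-0.44), CLDN4 (-0.23) and CDS1 (-0.21). EPCAM (-0.08), CLDN3 (-0.12) and GRHL2 (0.05) were not called. A rise of these genes as a set was therefore not seen. This line makes keratins such as KRT18 (0.26) itself, and centring removed the levels of all 23 genes, so admixed epithelial cells stay open. Cells that make only part of the lung genes and an effect of the enzyme stay open too, untested.

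Cell cycle genes were lower in the HS3ST2-labelled arrays. The array with high ribosomal RNA signal is argued against as the whole cause, since 32 of 36 genes were lower without it. The median of that signal was also above every control array in HS3ST2 replicates 1 and 2 (0.02 and 0.16). Not every ribosomal RNA probe set separated the groups. For example, a probe set stood at 0.43 in control replicate 1, against -0.09 and 0.09 in HS3ST2 replicates 1 and 2. Whether the signal differs between the groups beyond HS3ST2 replicate 3 is therefore not settled. Leaving out 1 array does not test a cause that moved it with the groups, which stays open. The list's mean ranged within a group by at most 0.143 of the difference between groups. This argues against variation of growth state among cultures only if the arrays of a group came from separate cultures. Whether replicates were separate transfections is not given in the sources used here. A growth difference that follows the groups, such as density at harvest, and an effect of the enzyme stay open and were not tested.

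The 6 arrays can be divided in 10 ways, too few for a share under 0.05. The labelled division gave 9220 probe sets, 4845 genes and 4 lists, and the highest of the others gave 0, 0 and 2, with 323 to 619 genes at an unadjusted p under 0.05 by limma. The labelled division was the only 1 of the 10 with as many. Each of the other divisions called 1 or 2 lists by camera although limma called 0 genes there. A camera call at the preset correlation therefore did not need called genes.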

How the results depend on the processing

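The robust fit and the probe set of largest SD were chosen after seeing the data. Cyclic loess, the filters at mean levels of 5 and 7 and the intensity trend, with and without a robust fit, need levels and were not run, and signal over background could not be judged. Of 104 named genes past the threshold, most picked for size or small p, 97 kept direction and call in every setting that measured them. Without the _x_at and _s_at probe sets 78 were measured, of which 71 kept both, and 26, NKX2-1, MAGEA6 and CDC20 among them, have only such probe sets and were not tested there. The other 7 changed only there: CXCL5, FBLN1, GDF15, HERPUD1 and NRG1 lost their call, and ITGB4 (-0.038) and LTBP3 (-0.096) turned. HS3ST2 was uncalled in every setting (0.022 to 0.22 over left-out arrays). Genes changed numbered 3777 to 4020 and probe sets 6299 to 7050 over left-out arrays. Of the 4845 genes of the reported result, 3617 to 3788 stayed called there. Genes numbered 3328 without the _x_at and _s_at probe sets (1667 higher, 1661 lower) and 5198 with the probe set of largest SD, and those also called in the reported result (3088 and 4069) all had its direction. The share higher was 45.6% to 50.1% over settings, against 46.9%. A change of at least 1 log2 left 508 probe sets, and an adjusted p under 0.01 left 4643. Camera called 4 lists, against 0 with an estimated correlation (3 at an unadjusted p under 0.05), 16 by fry, which does not compare a list with other genes, and 2 without the _x_at and _s_at probe sets. It called 3 to 5 over left-out arrays and 5 with array weights, the luminal list (0.0416) being added there and without control replicate 1 (0.0224). Whether the replicate numbers pair the arrays is not settled, since deviations of same-numbered arrays correlated only at 0.152, 0.041 and -0.083. Control replicates 1 and 2 correlated best with the HS3ST2 array of the same number, and control replicate 3 with HS3ST2 replicate 2 (0.182). The replicate block gave 4302 genes, of which 4090 were shared, 7705 probe sets and 4 lists, with 3 TGF-beta genes higher, 2 sterol genes lower and 1 leukocyte marker lower. Uncalled genes near 0 turned: without the _x_at and _s_at probe sets CDH2 (-0.094) and TCF7L2 (-0.0024), with the probe set of largest SD CDH2 (-0.094), TCF7L2 (-0.20) and MMP2 (-0.23), and MMP2 with quantile normalization (-0.0069) and array weights (-0.014). Over left-out arrays MMP2 ranged from -0.057 to 0.093, MMP9 from -0.14 to 0.17 and SDC4 from -0.0044 to 0.089. Some uncalled lists turned, with these adjusted p by camera unless fry is named. Proteases turned with the block (1), without control replicate 2 (0.946) and without HS3ST2 replicate 3 (0.99). Proteoglycan cores turned without the _x_at and _s_at probe sets (0.984), with the largest SD (0.865) and without HS3ST2 replicate 1 (0.995). Wnt turned without HS3ST2 replicate 3 (0.99) and fibroblast without control replicate 2 (0.946). Mesenchymal turned by fry (0.123), and sterol without the _x_at and _s_at probe sets (0.453). Over all left-out arrays, turned or not, the ranges were 0.846 to 0.997 for proteases and 0.877 to 0.995 for proteoglycan cores. They were 0.684 to 0.99 for Wnt and 0.875 to 0.995 for fibroblast. Beyond the fewer probe sets or arrays, the cause was not tested.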

Other observations

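The mucosal test was chosen after the trefoil factors and 1 member, MUC1, had been seen, and both class tests leave out genes already seen.

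Some genes of stomach and mucosal surfaces beyond those described were higher in the HS3ST2-labelled arrays. VSIG1, a stomach adhesion protein, was higher by 0.62 ± 0.06 log2 (SE, n = 3 per group), MUC5AC, a gel-forming mucin of stomach and airway, by 0.58 ± 0.06, GKN2, a gastrokine, by 0.45 ± 0.12 and FCGBP, a mucus protein, by 0.36 ± 0.05. These were 4 of 24 measured mucosal and stomach-type genes, with 0 lower by limma at an adjusted p under 0.05. Other mucins did not pass, with MUC1 at 0.06 and MUC2 at 0.10.

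A candidate explanation for the trefoil factor rise is a mucosal secretory programme. These 24 genes were not shown to be higher more often than other genes (Fisher's exact test, one-sided p = 0.295), which leaves it undecided. Among cancer-testis antigens, MAGEC1 (1.98 ± 0.10) and MAGEA12 (1.09 ± 0.14) were higher besides MAGEA6. Of 24 others, chosen without these, 0 were higher by limma, also at an unadjusted p under 0.05, and 1 was lower (Fisher's exact test, one-sided p = 1). The median change of these 24 was 0.0262 log2 (bootstrap interval -0.0768 to 0.119). These values argue against a rise of the 24 genes as a set. Centring removed their levels, which limits this argument. The test left out members already seen to be higher, so a rise of only part of the class stays open.

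Neighbouring genes tended to change together. Of 18540 windows of 51 measured genes in genome order, 178 had a median change beyond 0.135 log2, a size that the largest window passed in 5% of 200 shuffled orders. The windows joined into 13 segments, 7 higher and 6 lower, which held 918 genes. From UBAC1 to TUBBP5, 28 of 77 genes were lower and 0 higher, from SLCO5A1 to RBM12B-AS1, 34 of 93 were lower and 4 higher, and from STARD13 to WDFY2, 41 of 114 were higher and 2 lower. A hypothesis is that the cell populations differ in copies of these segments. The 178 windows are consistent with it but do not single it out, since shared regulation or base composition, which was not analysed here, may also move neighbours together.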
